A study of Rattus norvegicus with 15 samples.

How the data were processed

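RNA from the ventral tegmental area, the midbrain region that holds the dopamine neurons projecting to the nucleus accumbens and cortex, was measured on Affymetrix rat expression arrays in 15 rats. Per the labels, 7 rats drank ethanol and 8 were age-matched water controls, and each array came from 1 animal. The series title names alcohol-preferring rats and loss-of-control drinking, while its design text speaks of lines bred for high or low intake. The labels separate only ethanol from water, so that was the only comparison made. Ethanol animal number 3 was not analysed here. Litter, age, sex, the time from the last drink to death and the days of dissection and hybridization are not given in the sources used here, so no batch could be tested. Per the labels, biotin-labelled RNA was made from 25 ng of total RNA with a protocol of 2 amplification cycles. Such amplification shortens the copies toward the 3' end, so arrays can differ in how well they show the 5' part of a transcript.

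The values are on a log2 scale and were deposited by the authors, who made them with RMA per the submitters' processing notes. The software and version used for RMA are not given in the sources used here. RMA corrects the background, gives every array the same distribution of probe intensities and combines the probes of a probe set into 1 log2 value. It therefore removes any shift common to most transcripts, and it tends to compress differences of dim probe sets and of those close to the upper end of the scanner's range. The table held 31099 probe sets on 15 arrays with 0 missing values, and 0 columns of values were left unused. The 57 control probe sets were used only to judge RNA integrity and labelling. Detection calls for dim probe sets were not used here, so signal over background is known only through the mean level.

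Gene names came from the platform annotation kept by GEO, and symbols were looked up again by Entrez gene number in a RefSeq gene table of the GRCr8 assembly. Of the 31042 probe sets that were not controls, 20837 had 1 gene symbol, 425 had several and 9780 had no symbol listed. The Entrez number of 20758 of the probe sets with 1 symbol was found in the RefSeq table, and 0 symbols had changed. Probe sets with several symbols or no symbol were tested and counted but not named. The 1-symbol probe sets stood for 14224 genes. The array files name no genome assembly, so no chromosomal coordinates are given.

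Probe sets were kept if their mean over all 15 arrays reached the 40th percentile, a log2 value of 6.94, which left 18625. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over the 18625. An adjusted p below 0.05 was the threshold. Differences are ethanol minus water on the log2 scale, with limma's moderated standard error (SE). The fit was tested on simulated data drawn independently for each probe set from its mean and within-group SD in these arrays, with 200 changed probe sets among 18625. It recovered 74.6% of changes of 0.30 log2 units, 85.1% of those of 0.50 and 98.5% of those of 1 log2 unit. Of the 181 simulated calls, 9 were false, or 4.97%. The number of arrays limits the precision, and the median SE was 0.056 log2 units.

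Of 33 gene lists fixed in advance, 11 hold markers of cell types that a midbrain punch could contain and the others hold receptors, stress responses and metabolic pathways. Each gene was represented by the kept probe set with the highest mean, which gave 10256 genes. The 29 lists with at least 5 measured members were tested with limma's camera against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29. The same test was run with the correlation estimated from the data, and fry, which asks whether a list's genes move one way on balance, was run as well. The form of fry for changes in either direction was also computed and adjusted over the 29 lists. After the values had been seen, an exact permutation test of each list's mean over the arrays was added, because the preset correlation was far below the estimated one in several lists. It uses all 6435 ways of dividing 15 arrays into 7 and 8, is two-sided and is adjusted over the 29 lists. Its smallest possible p is 1.55e-04. Calls of single members were counted over all probe sets and adjusted over the list alone. The same exact test compared array quality measures and the first 5 principal components between the groups.

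The rule for naming genes took the 12 largest rises and the 12 largest falls among called probe sets with 1 symbol, skipping accession-like symbols, the 4 members with the smallest p in each called list, up to 4 members of every other list that passed when adjusted over the list alone, and a set of tissue reference genes. Named outside this rule, after their values were seen, are the list members Srebf2, Opalin, Itgam, Tmem119, Nr3c1, Nr3c2, Igfbp2 and Hbb, the unmeasured choroid plexus and ependymal markers, the leading genes Nefh, Nefl, Scn4b and Pvalb of the first principal component, and single genes of the closing section. The samples, the tests, the lists, the naming rule and the first set of alternatives were chosen before the data were examined. The alternatives changed the filter, the normalization, the moderation, the weights of arrays, a covariate for RNA integrity, the pairing by animal number, the set test and the choice of probe set, and left out each array in turn. A further 4 were added later besides the permutation test of lists: leaving out water animals 7 and 8 together, the first principal component as a covariate, the mean of the myelin list as a covariate, and the ribosome list without the ribosomal S6 kinases that its symbol pattern had also taken in. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.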

Results

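Expression was measured in the ventral tegmental area of 7 rats that drank ethanol and 8 rats that drank water, with 1 array per rat. The series title asks which genes differ in this region after loss-of-control drinking by alcohol-preferring rats, a line bred for high voluntary intake. Th, which encodes the rate-limiting enzyme of dopamine synthesis and marks the dopamine neurons of this region, averaged 14.94 ± 0.22 (SD, n = 7) log2 units in ethanol rats and 14.80 ± 0.26 (SD, n = 8) in water rats.

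Of the gene lists fixed in advance, cholesterol synthesis (median log2 -0.19) and oligodendrocyte and myelin transcripts (-0.17) were called lower and microglial markers (0.27) higher in ethanol rats by limma's camera, and the myelin and microglial calls were lost with an estimated correlation (adjusted p = 0.304 and 0.150). Complement C3, the central component of the complement cascade, rose most among named genes, from 8.23 ± 0.37 (SD, n = 8) to 9.50 ± 0.42 (SD, n = 7), a 2.40-fold difference (log2 1.26, SE 0.18, adjusted p = 0.00278). Gpr34, a receptor of microglia, rose 1.86-fold (log2 0.89, SE 0.11, adjusted p = 4.46e-04). Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase that corticosteroids induce in oligodendrocytes, fell to 0.571 of the water level (log2 -0.81, SE 0.13, adjusted p = 0.00592). The smallest p belonged to Cyp51, the sterol demethylase of cholesterol synthesis, which fell from 13.09 ± 0.06 (SD, n = 8) to 12.59 ± 0.05 (SD, n = 7; log2 -0.50, SE 0.03, adjusted p = 1.50e-06).

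Across the array, 173 of 18625 probe sets passed the threshold, or 0.929%, with 72 higher and 101 lower in ethanol rats. Those with 1 symbol stood for 125 genes, 53 of them higher and 72 lower. Differences were small: the median size among called probe sets was 0.33 log2 units, and 2 differed by 2-fold or more, C3 and an unnamed transcript that fell by 1.42 log2 units (chosen after its values were seen). In 116 of the 18625 tested probe sets, 88 of them called, the groups did not overlap, and chance gives that for 0.0311% of probe sets. At an unadjusted p below 0.01 there were 800 probe sets, 403 higher and 397 lower, against 186.3 by chance. The count of called probe sets fell to 100 without ethanol rat 7 and to 102 without ethanol rat 8. It was 305 (251 higher and 54 lower) with the mean of the myelin list as a covariate, a setting chosen after seeing the data. Of the 173 calls, 84 were among these 305.

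Besides C3 and Gpr34, the 12 largest rises included the carnitine and ergothioneine transporter Slc22a4 (log2 0.69), Jhy (0.60), the microglial lipid receptor Trem2 (0.52), Birc7 (0.48), Cbr3 (0.45), the protocadherin Pcdhb9 (0.41), the immune adaptors Tyrobp (0.41) and Fcer1g (0.40), the lipogenic transcription factor Srebf1 (0.39) and Acot4 (0.38). Besides Gpd1 and Cyp51, the 12 largest falls included Ugt8 (log2 -0.69), which makes the myelin lipid galactosylceramide, the stress-inducible mTOR inhibitor Ddit4 (-0.64), the fatty acid desaturase Scd (-0.58), the lipase Pnlip (-0.58), the sterol enzymes Tm7sf2 (-0.56) and Nsdhl (-0.51), the peptide Apln (-0.49), the acetyl-CoA synthetase Acss2 (-0.49), Pex11a (-0.49) and the transcription factor Nfil3 (-0.48). In each of these 24 genes all 7 ethanol rats lay on the same side of the water mean. Trem2, Srebf1, Gpd1, Nsdhl, Cyp51 and Apln each had another kept probe set that moved the same way at an unadjusted p below 0.05. The calls of Slc22a4 (without ethanol rat 1, 2, 5 or 8 or water rat 6), Scd (without ethanol rat 1) and Pex11a (in all but 4 of the 15 fits) ended when 1 array was left out, with adjusted p up to 0.0612, 0.0502 and 0.0974.

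**Figure D1:**
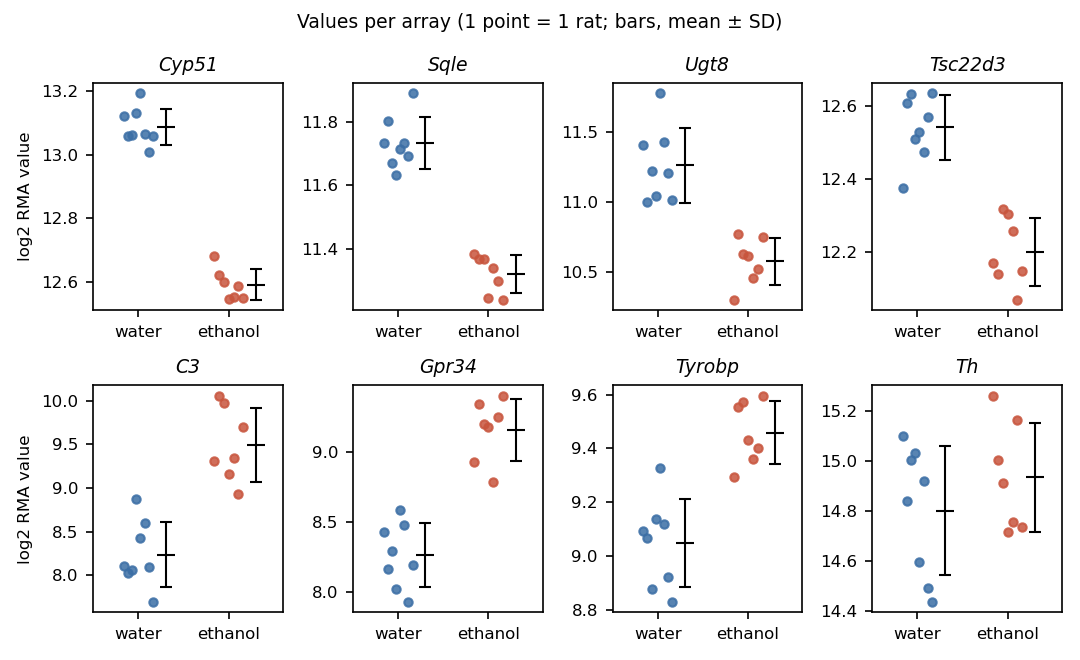
Log2 RMA values of 8 genes, 1 point per rat, in water (blue, n = 8) and ethanol (red, n = 7) rats, with bars for the mean and SD. Cyp51, Sqle, Ugt8 and Tsc22d3 fell and C3, Gpr34 and Tyrobp rose, while Th overlapped between the groups (log2 0.13, adjusted p = 0.667).

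Cholesterol synthesis enzymes fell together. Of the 13 measured members of this list, 6 fell when adjusted over all probe sets and 10 when adjusted over the list alone, none rose, and all 13 had lower means in ethanol rats. Sqle, the squalene epoxidase, fell from 11.73 ± 0.08 (SD, n = 8) to 11.32 ± 0.06 (SD, n = 7; log2 -0.41, SE 0.04, adjusted p = 6.18e-05). Msmo1 (log2 -0.38) and Dhcr7 (-0.31), enzymes of the later steps, fell as well. Srebf2, the transcription factor that drives the pathway, had a log2 difference of -0.019 (adjusted p = 0.902). The list median was -0.19, the camera adjusted p was 1.12e-17, and it was the only list called with an estimated correlation (adjusted p = 0.0167). The mean of the list was lower than the water mean in 7 of 7 ethanol rats, and its exact permutation adjusted p was 0.00451. The myelin list had a median of -0.17 in the same rats, with 5 of 14 members called and its list call lost with an estimated correlation (adjusted p = 0.304) and with fry (adjusted p = 0.0580).

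Oligodendrocyte and myelin transcripts fell in part. Of 14 measured members, 5 fell when adjusted over all probe sets, and adjusted over the list alone 8 fell and 1 rose. Ugt8 fell from 11.26 ± 0.27 (SD, n = 8) to 10.58 ± 0.17 (SD, n = 7; SE 0.11, adjusted p = 0.00413), and Fa2h, which hydroxylates the fatty acids of myelin lipids, fell by 0.43 log2 units, a call that ended without ethanol rat 7 (adjusted p = 0.0567). The tight junction protein Cldn11 (log2 -0.25) and the myelin proteolipid Mal (-0.39) fell too, but their calls ended in 11 and 9 of the 15 fits with 1 array left out, with adjusted p up to 0.0879 and 0.0838. The member that rose when adjusted over the list alone was Opalin (log2 0.20). Mbp, the major myelin basic protein, had log2 values of 16.02 ± 0.01 (SD, n = 7) and 16.05 ± 0.04 (SD, n = 8), near the upper end of the scanner's range, and did not pass (adjusted p = 0.637). The list median was -0.17 (camera adjusted p = 7.88e-09, and adjusted p = 0.304 with an estimated correlation). The list mean was lower than the water mean in 7 of 7 ethanol rats (exact permutation adjusted p = 0.0308). Water rats 2, 4 and 8 lay within the ethanol range of this mean.

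Microglial markers rose in part. Of 13 measured members, 4 rose when adjusted over all probe sets and 9 when adjusted over the list alone, none fell, and all 13 had higher means in ethanol rats. Tyrobp, the adaptor of Trem2, rose from 9.05 ± 0.16 (SD, n = 8) to 9.46 ± 0.12 (SD, n = 7; SE 0.07, adjusted p = 0.00824). The lysosomal protease Ctss rose by 0.36 and the leukocyte phosphatase Ptprc by 0.38 log2 units, and both calls ended in most fits with 1 array left out (12 and 13 of 15, with adjusted p up to 0.103 and 0.105). Aif1, a general microglial marker, was at log2 0.37 (adjusted p = 0.0908), and Itgam and Tmem119 were at 0.056 and 0.059. Over the list the median was 0.27 (camera adjusted p = 3.62e-10, and adjusted p = 0.150 with an estimated correlation). The list mean was higher than the water mean in 7 of 7 ethanol rats (exact permutation adjusted p = 0.0150), though water rat 5 lay within the ethanol range. The list of innate immune and NF-kappaB genes was not called (camera adjusted p = 0.634): of its 11 measured members, Irf1 rose (log2 0.22, adjusted p = 0.0438), a call that ended in 12 of the 15 fits with 1 array left out, and Nfkbia passed only when adjusted over the list alone (log2 -0.38).

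Corticosteroid-responsive transcripts fell in part. Of 11 measured members, 3 fell when adjusted over all probe sets and 5 when adjusted over the list alone, and none rose. Tsc22d3, a direct target of the glucocorticoid receptor, fell from 12.54 ± 0.09 (SD, n = 8) to 12.20 ± 0.09 (SD, n = 7; log2 -0.34, SE 0.05, adjusted p = 0.00201). Klf9 fell by 0.29 and Errfi1 by 0.40 log2 units, with calls that ended in 5 and 12 of the 15 fits with 1 array left out (adjusted p up to 0.0647 and 0.0886). Sgk1 had the largest difference of the list (log2 -0.63, SE 0.16) and passed only when adjusted over the list alone. The receptors Nr3c1 (log2 0.038) and Nr3c2 (0.0042) did not pass. The list median was -0.29 (camera adjusted p = 7.72e-07, and adjusted p = 0.150 with an estimated correlation). The list mean was lower than the water mean in 7 of 7 ethanol rats (exact permutation adjusted p = 0.0308). Water rats 4 and 8 lay within the ethanol range of this mean. With the myelin list mean as a covariate, the camera call ended (camera adjusted p = 0.0520), at a median of -0.21.

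Immediate early transcripts, which neurons induce within minutes of activity, were lower as a group. Of 10 measured members none passed over all probe sets, 4 fell when adjusted over the list alone, and all 10 had lower means in ethanol rats. Egr1 was at 9.04 ± 0.41 (SD, n = 7) against 9.66 ± 0.21 (SD, n = 8; log2 -0.62, adjusted p = 0.0689), and Fos was at log2 -0.59 (adjusted p = 0.0872). Dusp1 (-0.42) and Nr4a3 (-0.38) also passed over the list alone. The list median was -0.24 (camera adjusted p = 8.27e-05, and adjusted p = 0.150 with an estimated correlation). The list mean was lower than the water mean in 6 of 7 ethanol rats (exact permutation adjusted p = 0.0237). With the myelin list mean as a covariate the camera adjusted p was 0.0520, which ended the call. The median was then -0.25, against -0.24 without the covariate.

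**Figure D2:**
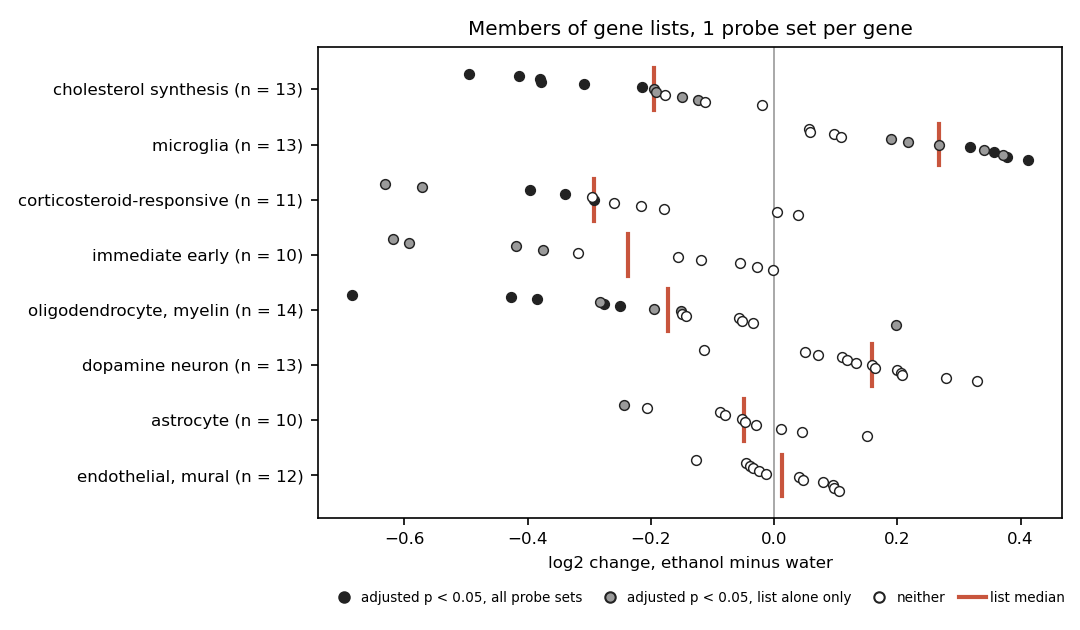
Log2 change (ethanol minus water, n = 7 and 8 rats) of each measured member of 8 gene lists, 1 point per gene, with black points past an adjusted p of 0.05 over all probe sets, grey points past it over the list alone and red bars at the list median. All 13 cholesterol synthesis genes lie below 0 and all 13 microglial markers above it, while the astrocyte and endothelial lists scatter around medians of -0.049 and 0.014.

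No dopamine neuron marker passed the test on its own. None of the 13 measured members passed over all probe sets or over the list alone, although 12 had higher means in ethanol rats, among them Gch1 (log2 0.33, SE 0.15), Otx2 (0.28, SE 0.17), Ddc (0.21, SE 0.11), Slc18a2 (0.21, SE 0.11), Drd2 (0.20, SE 0.13) and the dopamine transporter Slc6a3 (0.16, SE 0.12). The list was called higher by camera (median 0.16, adjusted p = 0.0248; adjusted p = 0.728 with an estimated correlation). Its list mean was higher than the water mean in 5 of 7 ethanol rats and did not pass the exact permutation test (adjusted p = 0.517). The camera call ended without ethanol rat 1, 6 or 7 or water rat 5, 7 or 8, with medians from 0.081 to 0.16. Markers of other neurons overlapped between the groups: Gad1 was at log2 0.11 (SE 0.24) and Slc17a6 at -0.29 (SE 0.41).

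The list of choroid plexus, ependymal and meningeal transcripts was called lower by camera, but no probe set of Ttr, Kl, Folr1, Foxj1 or Kcnj13, its markers of choroid plexus and ependyma, passed the filter on dim probe sets, so the call does not rest on them. Of the 5 measured members none passed over all probe sets, and the collagen Col1a2 (log2 -0.68, SE 0.19) and the growth factor Igf2 (-0.58, SE 0.17) fell when adjusted over the list alone. Igfbp2 was at -0.32, Dcn at -0.30 and Ptgds at 0.082. Over the 5 genes the median was -0.32 (camera adjusted p = 0.0382, and adjusted p = 0.304 with an estimated correlation). The list mean was lower than the water mean in 7 of 7 ethanol rats (exact permutation adjusted p = 0.0457). Water rats 3, 6 and 8 lay within the ethanol range of this mean. The camera call ended without ethanol rat 1, 2 or 6 or water rat 4, 5 or 7, with medians from -0.42 to -0.26. Among astrocyte markers, 10 measured, the gap junction protein Gjb6 passed over the list alone (log2 -0.24), and Gfap was at 0.15 (SE 0.20). Neither the astrocyte list (camera adjusted p = 0.0941) nor the endothelial and mural list (0.776) was called.

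The cytosolic ribosome list was called slightly higher. Of its 49 measured members, 7 are ribosomal S6 kinases, which are not ribosomal proteins. None of the 49 passed over all probe sets and 6 rose when adjusted over the list alone, with 42 positive in sign. Rpl12 was at log2 0.14, Rpl5 at 0.10, and Rpl19 and Rpl3 at 0.092 and 0.088. The median of the 49 was 0.062 (camera adjusted p = 3.72e-11, and adjusted p = 0.304 with an estimated correlation). The list mean was higher than the water mean in 7 of 7 ethanol rats (exact permutation adjusted p = 0.0150). Water rat 1 lay within the ethanol range of this mean. Without the 7 kinases, a setting chosen after seeing the data, 39 of 42 were positive, 9 rose when adjusted over the list alone, and the median was 0.065 (camera adjusted p = 1.76e-13; adjusted p = 0.319 with an estimated correlation; exact permutation adjusted p = 0.0165). Mitochondrial respiration genes were called lower by camera (86 measured, median -0.037, adjusted p = 1.96e-04; adjusted p = 0.924 with an estimated correlation), none passed over the list alone, and the exact permutation adjusted p was 0.660. The members with the smallest p were Sdhaf2 (log2 -0.11), Cox7a1 (-0.15), Ndufs4 (-0.067) and Ndufaf7 (-0.12). Heat shock proteins were called lower by camera (12 measured, median -0.053, adjusted p = 0.0187; adjusted p = 0.442 with an estimated correlation), none passed over the list alone, and the exact permutation adjusted p was 0.0744. Hspb1 and Cryab were at -0.33 each, Bag3 at -0.33 and Dnajb1 at -0.17. The calls of the mitochondrial and heat shock lists ended without water rat 8, at medians of -0.024 and -0.031. In settings chosen after seeing the data, the mitochondrial median was -0.0055 without water rats 7 and 8. With the first principal component as a covariate it was 0.0021, so its direction was not kept.

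The other 19 tested lists were not called, with camera adjusted p from 0.0526 for cholinergic receptors (6 measured, median 0.21) to 0.984 for second messenger kinases. Besides the astrocyte, endothelial and innate immune lists, they were the GABA neuron, general neuron, glutamate receptor, GABA receptor, cholinergic receptor, neuropeptide, ethanol-sensitive channel, ethanol metabolism, unfolded protein, glutathione, clock, synaptic vesicle, growth factor, chromatin, kinase and proteasome lists. No GABA or glutamate receptor subunit and no neuropeptide passed, over all probe sets or over its list alone. In the ethanol and acetate metabolism list, Acss2 fell (adjusted p = 0.00278) and none of the other 9 members passed. Members of other lists that passed over all probe sets were the clock repressor Nr1d1 (log2 0.35, adjusted p = 0.0477), the kinase Prkcd (0.23, adjusted p = 0.0493) and the immunoproteasome subunit Psmb9 (0.36, adjusted p = 0.0477), and each of these calls ended in 13 of the 15 fits with 1 array left out. Adjusted over the list alone, Cry1 (-0.19), Dbp (0.13), Gstp1 (0.19), Gsta4 (0.21), Gclm (-0.18), Ezh2 (-0.34), Rgs9 (0.21) and Crem (-0.13) also passed. The remaining 4 lists had under 5 measured members and were not tested: oligodendrocyte precursors (4, median -0.014), serotonin receptors (3, median 0.11), neighbouring nuclei (2, median -0.027) and blood, with Hbb alone (-0.17, SE 0.19).

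No measure of RNA integrity passed a test between the groups. The 3'-minus-5' difference of the control transcripts averaged 1.08 ± 0.05 (SD, n = 7) in ethanol and 1.11 ± 0.05 (SD, n = 8) in water rats (exact permutation p = 0.250). None of 9 quality measures passed after adjustment, the smallest p being that of each array's median correlation with the others, 0.992 in ethanol and 0.991 in water rats (exact permutation p = 0.0325, adjusted p = 0.292). The first principal component, 30.7% of the variance, did not follow ethanol (exact permutation p = 0.290). Its leading genes included the neurofilaments Nefh and Nefl, the sodium channel subunit Scn4b, the calcium-binding protein Pvalb of fast-firing neurons and the vesicular glutamate transporter Slc17a6, and water rats 7 and 8 had its highest scores. The third component, 8.97% of the variance, differed in mean between the groups (exact permutation p = 7.77e-04, adjusted p = 0.00389), though water rat 8 scored within the ethanol range. No component differed between the groups when each probe set was scaled to unit variance. Without water rats 7 and 8, 147 probe sets were called and 6 lists, and the dopamine neuron, choroid, heat shock and mitochondrial lists lost their camera calls.

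**Figure D3:**
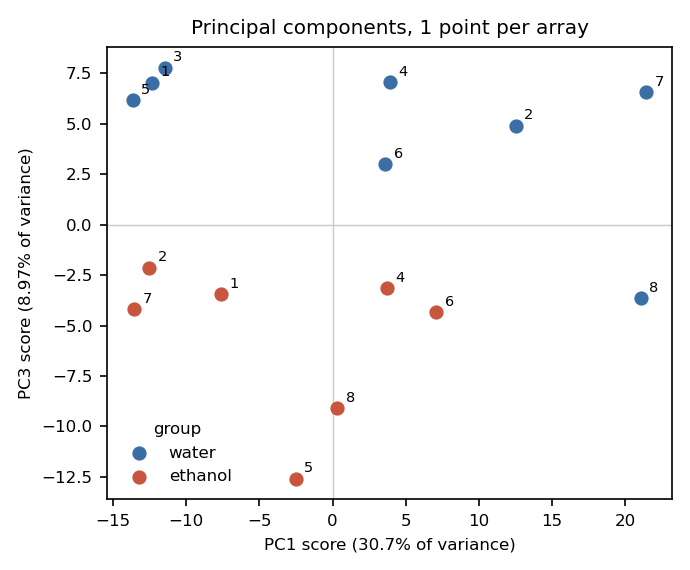
Scores of the 15 arrays on the first (horizontal, 30.7% of the variance) and the third (vertical, 8.97%) principal components of the log2 values, with water rats in blue, ethanol rats in red and animal numbers beside the points. All 7 ethanol rats lie below 0 on the third component, where 7 of the 8 water rats lie above 0, and water rats 7 and 8 lie farthest right.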

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

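The tests of blood, of cell shares, of time of day and of oligodendrocytes in the corticosteroid list, and the settings with the first principal component or the myelin mean as a covariate, were chosen after the results they bear on had been seen. In 9 of 214 group-wise sets of values, 1 array lay far from the rest of its group, where chance gives about 10.7, so their number is no more than chance gives. Water rat 8 had a Cbr3 log2 value of 6.85 (others 7.10 to 7.31), an interquartile range of 3.77 (others 3.85 to 3.91) and a score of -3.64 on the third principal component (the others all above 0, up to 7.79). In ethanol rat 5, Gjb6 was at 10.92 (others 11.21 to 11.38), and the mean of the cholesterol synthesis list was at 11.13 (others 11.29 to 11.34). In ethanol rat 1, Ctss was at 13.25 (others 13.46 to 13.58) and Rpl19 at 15.01 (others 14.93 to 14.96). Ethanol rat 8 had a value of 8.53 for the Trem2 probe set with the smaller change (log2 0.32; others 8.16 to 8.25). Water rat 4 had hybridization controls at 13.74 (others 13.16 to 13.41).

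Random divisions of the 15 arrays into 7 and 8 gave a count of called probe sets as large as 173 in 1 of 100 cases, the real one, and the highest other count was 1. For the 800 probe sets at an unadjusted p below 0.01 it was again 1 of 100, with 570 as the highest other count. Chance is thus unlikely for both counts, and 1 of 100 is the smallest share this test could give. It is not excluded for the number of lists called by camera with the preset correlation: 13 of 100 divisions called 10 or more lists, and the highest other count was 14.

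The first pattern is the fall of cholesterol synthesis transcripts. With the myelin list mean as a covariate the median of the 13 members was -0.24 and 5 members stayed called, with the first principal component it was -0.23 with 6 called, and with the 3' measure it was -0.20 with 6 called. These fits argue against a linear relation to those measures, as seen within groups, as the whole cause. The first component and the 3' measure did not pass a test between the groups (exact permutation p = 0.290 and 0.250). Adding them could therefore move the median little. The median SE rose from 0.049 to 0.065 with the myelin mean. Within groups its relation to the sterol list mean was undecided (Pearson r 0.118, 95% interval -0.44 to 0.61, permutation p = 0.665). Fewer oligodendrocytes are therefore not excluded as a cause. A link to corticosteroid exposure stays open, since within groups the sterol and corticosteroid list means had a Pearson r of 0.0486 (permutation p = 0.853, adjusted p = 0.853 over 7 relations, 95% interval -0.495 to 0.565; Spearman rho 0.111, permutation p = 0.702; r 0.224 without the 2 arrays farthest from the median), an interval too wide to decide. A lowering by ethanol drinking itself may account for the pattern, as a hypothesis found and tested on the same arrays.

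The second pattern is the higher microglial list, whose camera call was lost with an estimated correlation (adjusted p = 0.150). With the first principal component as a covariate the median was 0.20 with 3 members called, against 0.27 and 4 without it. This argues against a linear relation to that component, as seen within groups, as the whole cause. Dissection differences along other components were tested for no pattern here. The second component (13.2% of the variance) had Slc6a4, Gad1 and Slc17a6 among its leading genes. Its scores did not differ between the groups (exact permutation p = 0.292). Blood left in the tissue is argued against by Hbb, at -0.17 with an upper 95% bound of 0.25, and a lower share of neurons and oligodendrocytes by the endothelial and mural median of 0.014 and the astrocyte median of -0.049, each below the microglial median by more than the spread of its members (SD 0.073 and 0.11). Infiltrating leukocytes cannot be told apart from microglia here, because 2 of their markers were measured, Lyz2 (0.15) and Plac8 (0.41), with a median of 0.28. More microglia, or more transcripts per microglial cell, may underlie it, and cells were not counted. Of the 13 members, 9 passed over the list alone, among them Tyrobp at 0.41 (SE 0.070). C1qb (0.11, SE 0.084), C1qc (0.097, SE 0.070), Tmem119 (0.059, SE 0.069) and Itgam (0.056, SE 0.084) did not pass. These values argue against an equal rise of every marker, and so against more microglia alone, as far as probe sets respond alike.

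The third pattern is the lower corticosteroid-responsive list, whose camera call was lost with an estimated correlation (adjusted p = 0.150). Its median was -0.33 with the first principal component as a covariate (4 members called) and -0.25 with the 3' measure (3 called). This argues against a linear relation to either, as seen within groups, as the whole cause. Neither measure passed a test between the groups, so adding them could move the median little. With the myelin mean as a covariate the median moved from -0.29 to -0.21 and 1 member stayed called instead of 3, while the median SE rose from 0.11 to 0.13, so fewer oligodendrocytes cannot be told apart from lower induction in part of the list. Within groups the corticosteroid and myelin list means had the largest r of the 7 relations, which does not settle it (Pearson r 0.527, 95% interval -0.00532 to 0.826, permutation p = 0.0623, adjusted p = 0.436; Spearman rho 0.504, permutation p = 0.0652; r 0.38 without the 2 farthest arrays). A different time of day at death stays open as well. A clock contrast (the mean of Nr1d1, Nr1d2, Dbp, Per3, Tef and Hlf minus that of Bmal1, Npas2, Clock and Cry1) was put together after the clock genes had been seen, so its difference between the groups tests nothing, and its relation to the corticosteroid list mean within groups was undecided (Pearson r 0.0758, 95% interval -0.474 to 0.583, permutation p = 0.810, adjusted p = 0.853; Spearman rho 0.125, permutation p = 0.676; r 0.140 without the 2 farthest arrays). Lower corticosteroid exposure of the ethanol rats may account for the pattern and was not measured.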

How the results depend on the processing

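The setting with water rats 7 and 8 left out, those with the first principal component or the myelin mean as covariates, the ribosome list without S6 kinases, and the permutation of list means were chosen after seeing the data. The sterol list median kept its direction and call in all 33 alternatives, and the count at an unadjusted p below 0.01 stayed within 1.5 times 800. The count of 173 ranged from 100 (without ethanol rat 7) to 180 (without water rat 8) when 1 array was left out, and was 102 without ethanol rat 8. It was 287 at an adjusted p of 0.10 and 305 (251 higher and 54 lower) with the myelin mean as a covariate, a term that itself differs between the groups. Of the 173 calls, 84 were among these 305. With the animal number as a replicate block over 14 arrays the count was 59, against 130 without the block on the same arrays. Whether animals with the same number deviate together was not settled: 4 of 7 correlations of their deviations exceeded 0.1, in a range of -0.415 to 0.295, and 1 of the 7 ethanol arrays correlated best with its own number. The number of lists called was 1 with an estimated correlation, 5 with fry, 6 without water rats 7 and 8 and 6 with the myelin covariate. Calls were lost, medians being unaltered, with an estimated correlation for the dopamine (0.16), myelin (-0.17), microglia (0.27), choroid (-0.32), immediate early (-0.24), heat shock (-0.053), corticosteroid (-0.29), ribosome (0.062) and mitochondrial (-0.037) lists, and with fry for the dopamine (0.16), myelin (-0.17), choroid (-0.32), heat shock (-0.053) and mitochondrial (-0.037) lists. The exact permutation of list means did not call the dopamine (0.15), heat shock (-0.11) and mitochondrial (-0.040) lists. Calls also ended without water rats 7 and 8 for the dopamine (0.085), choroid (-0.33), heat shock (-0.017) and mitochondrial (-0.00548) lists, and with the first component for the same lists (0.10, -0.32, -0.030 and 0.0021, in that order). With the myelin covariate they ended for the dopamine (0.029), myelin (-0.00242), choroid (-0.53), immediate early (-0.25) and corticosteroid (-0.21) lists. The loss for the myelin list was fixed in advance, since its own mean was the covariate. The choroid call also ended with median centring (-0.34) and array weights (-0.34). With 1 array left out, medians ran from 0.081 to 0.22 for the dopamine list, from -0.45 to -0.26 for the choroid list, from -0.078 to -0.031 for the heat shock list and from -0.056 to -0.022 for the mitochondrial list. The difference of Gad1, never called, ranged from -0.030 (without ethanol rat 5) to 0.23 with 1 array left out, and its sign turned also without water rat 7 (-0.028), without water rats 7 and 8 (-0.015) and with the first component (-0.020). Slc17a6 turned without water rats 7 and 8 (0.045) and with the first component (0.13), and Otx2 with the myelin covariate (-0.0733). No component differed between the groups (0 of 5) when probe sets were scaled to unit variance. Of 40 called named probe sets, 26 stayed called whichever array was left out, and in 77 of 465 values under other settings a call was lost, with 0 reversals. Leaving out arrays costs power by construction, and otherwise the cause was not tested. Depth is limited by signal over background, which was not used here: without the filter on dim probe sets 139 were called, and with the stricter one 116.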

Other observations

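Single genes outside the fixed lists and the naming rule also passed over all probe sets, picked here after their values were seen and not tested as a group. Those that rose include the transcription factor Irf8, which myeloid cells need (log2 0.37), the inhibitory receptor Cd33 (0.37), the fatty acid receptor Gpr84 (0.36), the tetraspanin Cd53 (0.35), Ly86 (0.32), the lysosomal protein Laptm5 (0.30) and the inflammasome adaptor Pycard (0.27), while the fixed list of innate immune and NF-kappaB genes was not called (camera adjusted p = 0.634, exact permutation adjusted p = 0.910). The proteasome activator Psme1 (0.22), Abca1, which exports cholesterol (0.36), and Npc2, which moves it out of lysosomes (0.26), rose as well. Among those that fell were Acat2 (log2 -0.35), Hsd17b7 (-0.33) and Fads1 (-0.21).

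Clock transcripts moved apart without shifting as a list. Of 16 measured members 8 had positive and 8 negative differences, the list was not called by camera (adjusted p = 0.776), and limma's fry called it for changes in either direction (adjusted p = 2.7e-06). That form of fry was not particular to the clock list. Among lists that camera did not call, it also called the innate immune (adjusted p = 0.0142), glutathione (0.0339) and ethanol metabolism (0.0356) lists. Nr1d1 (log2 0.35) and Dbp (0.13) lay above the water mean in 7 of 7 ethanol rats and Cry1 (-0.19) below it in 7 of 7. Single values of Dbp and Cry1 overlapped between the groups. Nr1d1 alone passed over all probe sets (adjusted p = 0.0477), a call that ended in 13 of the 15 fits with 1 array left out (adjusted p up to 0.114). Nfil3, which opposes Dbp at shared promoters, was among the largest falls (-0.48), and the clock-controlled Usp2 fell by 0.48 (chosen after its values were seen).

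Whether further sterol and lipid genes were lower was asked of 15 measured genes outside the fixed list whose values had not been looked at. Genes already seen to fall, such as Tm7sf2, Nsdhl, Acat2 and Hsd17b7, were left out, so the set leans toward no fall and does not measure the pathway as a whole. The median of the 15 was -0.076, and 11 of 15 had lower means (exact sign test p = 0.119), so the question was left open. Stard4 (-0.24), Aacs (-0.18) and Ebp (-0.14) had the most negative values, and none passed over all probe sets. If sterols had accumulated, targets of the liver X receptor could rise. Abca1 and Srebf1, already seen to rise, were left out, so the set leans toward no rise. The 11 genes measured included Nr1h2 (-0.089), which encodes a liver X receptor itself. Their median was 0.077 and 8 were higher. The difference of their mean was 0.055 (95% interval -0.031 to 0.14, exact permutation p = 0.1998), so this hypothesis was left open.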
